A study of Homo sapiens with 13 samples.

How the data were processed

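The study profiled RNA from 2 established human breast cancer lines after fatty acid beta-oxidation was modified. Per the labels, cells grew in DMEM with 5% FBS, SUM159 received lentivirus for a CPT1 or scrambled hairpin, and SUM149 received 100 uM etomoxir for 1 week or water. Total RNA was extracted with a column kit and made into libraries by standard Illumina protocols, per the labels' protocols. The deposited values are read counts per gene, 1 column for each of the 13 libraries, neither scaled for depth nor for length. Reads were trimmed with Trim Galore, aligned to hg38 with STAR and counted with featureCounts, per the submitters' processing notes. Versions, annotation release, strand setting and the treatment of reads with several hits are not given in the sources used here. All 37 genes of the mitochondrial genome were listed at 0 in every library, so no mitochondrial genome-encoded list was tested. Symbols that occurred more than once were kept apart by their Ensembl identifiers. Gene positions, transcript lengths and GC content were taken from GENCODE on GRCh38, the same build as hg38, by Ensembl identifier. Length and GC are those of the longest annotated transcript of a gene, which can exceed the one expressed, so a length trend may be removed incompletely.

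From the counts, library sizes were scaled with TMM factors and genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Differences were tested with edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each line was fitted alone for its own comparison, 3 shCPT1 against 4 scramble libraries and 3 etomoxir against 3 water libraries, and all 13 libraries were fitted for the difference between the effects. Values per library are CPM of all counted reads, without TMM factors, given as mean ± SD. Fold changes come from the fit with TMM factors, so they can differ slightly from ratios of these means. Log2 fold changes carry a standard error. Total counts ranged from 14622929 to 20082392, so that 1 read is about 0.050 to 0.068 CPM. Each standard error was computed as the absolute log2 fold change over the square root of the F statistic. It is approximate, and can be too small for large changes of genes with few reads in a group, such as OTUD6A. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

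Before the data were examined, 35 gene lists, the comparisons, the tests, the alternatives and the rule for naming genes were fixed, except where a choice is said to have been made after seeing the data. The lists cover fatty acid and cholesterol metabolism, respiration, glycolysis, stress responses, hormone and lineage markers, adhesion, the cell cycle, inflammation, ribosomes, histones and markers of leucocytes and endothelium. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Fry tested whether the members of a list moved, on balance, in 1 direction. The leucocyte and endothelial list had too few tested members in SUM159. The named genes were CPT1A, CPT1B, CPT1C, ESR1, PGR and SRC, the 10 largest increases and 10 largest decreases per comparison, and up to 4 called members per list with the smallest adjusted p. Some of the genes this rule named are not reported here. The largest changes were taken among called genes with a mean of at least 5 CPM and no overlap between groups. For the comparison of both effects, the rule named 8 genes higher in both, 8 lower in both and 8 in opposite directions, by the smaller of their absolute fold changes. Other genes (NQO1 in SUM149, LINC00472, ALPG and the neighbours and PPAR genes of the closing section) were chosen after their values were seen.

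The alternatives were RLE factors, total counts alone, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, 1 fit over all 13 libraries, the replicate number as a block, counts thinned to the smallest library, and each library left out in turn. For the lists they were an estimated correlation and fry. A rank-based camera test, with and without a trend on transcript length removed, was added after seeing the data. The procedure was tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 3-fold. For SUM159 (14578 genes) it called 82 and 100 of them with 7 false calls, for SUM149 (14749 genes) 90 and 96 with 13 false calls, and for the difference (16636 genes) 65 and 93 with 7 false calls. The simulated changes were few, as many up as down, and drawn independently per gene. In the data 62.6% of tested genes were called in SUM159 and 64.4% in SUM149. The simulation thus cannot show how scaling and false calls behave where most genes change. Libraries of the same group had correlations of 0.992 to 0.995 and differed by more than counting noise (chi-square per degree of freedom 1.69 to 8.40), so none is a copy of another.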

Results

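RNA sequencing measured read counts per gene in 13 libraries from 2 established human breast cancer cell lines in which fatty acid beta-oxidation was modified. SUM159 cells carried a lentiviral short hairpin RNA against CPT1 (shCPT1, 3 libraries) or a scrambled hairpin (scramble, 4 libraries). SUM149 cells received 100 uM etomoxir, an inhibitor of carnitine palmitoyltransferase 1, for 1 week (3 libraries), or water (3 libraries). Carnitine palmitoyltransferase 1 (CPT1) makes the acylcarnitines with which long-chain fatty acids enter mitochondria. Total counts were 18767351, 20082392, 19205942 and 19580376 in scramble replicates 1 to 4 and 16312188, 17194343 and 18656429 in shCPT1 replicates 1 to 3. They were 19027408, 14622929 and 18366191 in water replicates 1 to 3 and 16412030, 15707289 and 16377705 in etomoxir replicates 1 to 3. The labels do not say whether replicates are separate cultures, so each p-value measures the spread between these libraries, which may be technical spread. Strand setting and the handling of reads with several hits are not given in the sources used here. Counts of near-identical copies (AKR1C1 and AKR1C3, ALPP and ALPG, ribosomal protein genes and their pseudogenes) and of overlapping or antisense genes are therefore uncertain.

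CPT1A (ENSG00000110090, hg38 chromosome 11, 68754620 to 68844410), the most abundant of the 3 CPT1 genes in all 13 libraries, fell 7.27-fold in SUM159 with the hairpin. Its level was 26.96, 23.01, 24.78 and 25.18 CPM (reads scaled to library size) in scramble replicates 1 to 4 and 3.31, 2.91 and 3.86 CPM in shCPT1 replicates 1 to 3. The group means were 25.0 ± 1.6 (SD, n = 4) and 3.36 ± 0.478 (SD, n = 3), a log2 fold change of -2.86 (SE 0.110, edgeR adjusted p = 1.6e-15). In SUM149, CPT1A rose 1.48-fold with etomoxir, from 136.44, 136.29 and 123.22 CPM in water to 188.95, 193.29 and 207.84 CPM. That is a log2 fold change of 0.57 (SE 0.038, edgeR adjusted p = 2.61e-21). CPT1B and CPT1C had too few reads to be tested in SUM159, with 24 or fewer per library. In SUM149 the log2 fold change of CPT1B was 0.08 (SE 0.398, edgeR adjusted p = 0.867), with a sign that turned without water replicate 1 or etomoxir replicate 3. That of CPT1C was -0.26 (SE 0.268, adjusted p = 0.404), and ranged from -0.37 to -0.13 with each library left out. The labels name CPT1 without an isoform.

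**Figure D1:**
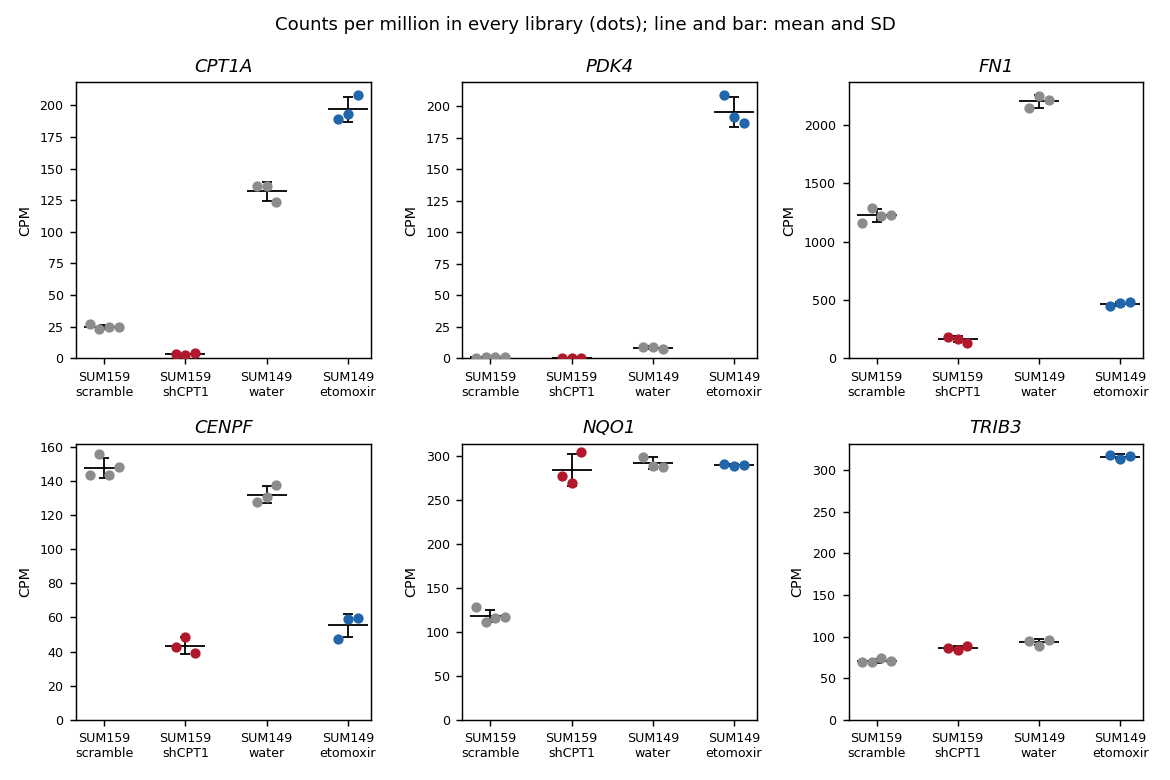
CPM of CPT1A, PDK4, FN1, CENPF, NQO1 and TRIB3 in each of the 13 libraries, 1 point per library, with the mean and SD of each group. CPT1A fell with the hairpin in SUM159 and rose with etomoxir in SUM149.

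The first comparison asks how the transcriptome of SUM159 with the CPT1 hairpin differs from that with the scrambled hairpin. The samples hold no second CPT1 hairpin and no rescue. Effects of lower CPT1A, other effects of the hairpin and differences between the cell populations therefore cannot be told apart. With shCPT1, genes of the NRF2 antioxidant response rose and NF-kappaB and inflammatory genes fell. Mesenchymal markers and G2 and M phase genes mostly fell, though their calls were lost with an estimated correlation (adjusted p = 0.235 and 0.213). NQO1, a quinone reductase of the NRF2 response, rose 2.44-fold, from 117.8 ± 7.19 CPM (SD, n = 4) to 283.2 ± 18.3 CPM (SD, n = 3). FN1, the gene of the matrix protein fibronectin, fell 7.40-fold, from 1224 ± 51.7 to 162.9 ± 25.7 CPM. MKI67, a marker of proliferating cells, fell 3.60-fold, from 220.8 ± 24.0 to 60.5 ± 9.08 CPM, well beyond the median log2 fold change of G2 and M phase genes (-0.30). Of 14949 genes tested, 4590 were higher and 4771 lower with shCPT1 (edgeR, adjusted p under 0.05), 628 and 949 of them by at least 2-fold.

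The largest rise was that of OTUD6A (ENSG00000189401, chromosome X, 70062491 to 70064179), which encodes a deubiquitinase. It went from 0.413 ± 0.101 to 225.7 ± 8.79 CPM, 547-fold higher (log2 fold change 9.10, SE 0.097, edgeR adjusted p = 6.5e-26). That SE is likely too small, given the few reads in scramble. ALPP, placental alkaline phosphatase (ENSG00000163283, chromosome 2, 232378534 to 232382889), rose 23.7-fold to 247.8 ± 14.2 CPM. MIR30A (ENSG00000207827, chromosome 6, 71403551 to 71403621) rose 13.4-fold. It had reads in all 7 libraries made with lentivirus and none in the other 6, and the surrounding gene LINC00472 did not move with it (log2 fold change 0.12, edgeR adjusted p = 0.649). The lentivirus libraries are all SUM159 and the others all SUM149, so virus and line differ together. The remaining genes of the 10 largest rises were LINC01929 (log2 fold change 4.35), SHOC1 (4.29), CPXM1 (3.71), RYR2 (3.64), C1QTNF6 (3.61), AKR1C1 (2.95) and PCSK2 (2.80). Among the 10 largest falls, GPNMB, a glycoprotein of lysosomes and melanosomes (ENSG00000136235, chromosome 7, 23235967 to 23275108), went from 31.9 ± 1.5 to 0.743 ± 0.249 CPM, 41.6-fold lower. APOE, the apolipoprotein of lipid transport, fell 15.4-fold (log2 fold change -3.94, SE 0.096), and C3, the central complement component, fell 11.2-fold from 381.9 ± 15.8 to 33.4 ± 3.51 CPM. The others were AC013457.1 (-6.13), CACNA2D1 (-4.71), NTN1 (-4.31), GNAO1 (-4.26), LAMA1 (-4.13), GALNT15 (-3.74) and GALNT14 (-3.38). AC013457.1 lies in a stretch of chromosome 2 from 118.0 to 149.2 Mb whose 70 tested genes had a median log2 fold change of -0.39, against 0.03 for the rest of the chromosome. ESR1, the estrogen receptor, had 6 or fewer reads per SUM159 library, and PGR, the progesterone receptor, had none. SRC, the tyrosine kinase, fell from 62.2 ± 2.15 to 42.1 ± 0.484 CPM (log2 fold change -0.54, SE 0.056, edgeR adjusted p = 1.99e-08).

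Of 33 gene lists tested in SUM159 with camera, 11 were called higher and 7 lower, and the NRF2 and NF-kappaB lists held their call with an estimated correlation. Of 25 tested NRF2 targets, 22 rose and 1 fell, with a median log2 fold change of 0.71 (camera adjusted p = 5.68e-22, and adjusted p = 0.0175 with an estimated correlation). AKR1C1 (2.95), AKR1C3 (2.38), NQO1 (1.29) and EPHX1 (1.19), enzymes that reduce or hydrolyse reactive compounds, were among them. None of 23 NF-kappaB and inflammatory genes rose and 20 fell (median -0.98, camera adjusted p = 7.32e-08, and adjusted p = 0.0215 with an estimated correlation). SOD2, mitochondrial superoxide dismutase, went from 406.1 to 199.2 CPM, NFKB2 fell by 0.98 and the chemokine CXCL2 by 1.47 on the log2 scale. Of 30 mesenchymal markers, 21 fell and 5 rose (median -0.40, camera adjusted p = 1.6e-05, but adjusted p = 0.235 with an estimated correlation). FN1 (-2.89), TNC (-1.72) and COL1A1 (-1.50) fell, while the collagen gene COL3A1 rose (1.48). Of 30 G2 and M phase genes, 20 fell and 3 rose (median -0.30, camera adjusted p = 2.33e-05, and adjusted p = 0.213 with an estimated correlation). They included the kinetochore genes CENPF (-1.74) and CENPE (-1.98), MKI67 (-1.85) and ASPM (-1.11). Their transcripts are long, from 8612 bases in CENPE to 12678 in MKI67, against a list median of 3037.5, and log2 fold changes in SUM159 fell with transcript length. With that trend removed the list median was -0.34.

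Genes of adhesion, YAP signalling, cholesterol metabolism and DNA methylation were also mostly lower in SUM159. Of 27 Src family and focal adhesion genes, 18 fell and 4 rose (median -0.29, camera adjusted p = 0.0012, and adjusted p = 0.352 with an estimated correlation). The integrins ITGB1 (-0.97) and ITGB5 (-1.18) fell, and LCK, a Src family kinase of lymphocytes, rose from 0.0901 to 4.70 CPM. Of 22 YAP and TEAD targets, 17 fell and 2 rose (median -0.46, camera adjusted p = 0.00128, and adjusted p = 0.403 with an estimated correlation). WWC1 (-1.19) and NT5E (-0.93) fell while CCN1 rose (0.79). Of 25 genes of cholesterol synthesis and uptake, 15 fell and 1 rose (median -0.19, camera adjusted p = 0.00102, and adjusted p = 0.101 with an estimated correlation). HMGCS1 (-0.78) and DHCR7 (-0.61), enzymes of cholesterol synthesis, were among those that fell. Of 19 genes of the DNA methylation machinery, 13 fell and 3 rose (median -0.35, camera adjusted p = 0.0211, and adjusted p = 0.324 with an estimated correlation), DNMT1 (-0.92) and TET3 (-0.96) among those that fell.

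Genes of fatty acid oxidation other than CPT1A mostly rose in SUM159. Of 21 mitochondrial beta-oxidation genes, 17 rose and 2 fell (median 0.40, camera adjusted p = 0.0295, and adjusted p = 0.404 with an estimated correlation). ACAA2 (0.56) and ETFA (0.48) rose, and the falls were CPT1A and PPARGC1A, a transcriptional coactivator of oxidative metabolism (-1.12). The call was lost without shCPT1 replicate 3 (camera adjusted p = 0.0519) and at a mean of at least 5 CPM (0.0653), within a range of 0.00543 to 0.0653 over the settings tried for camera with its preset correlation. Of 18 peroxisomal beta-oxidation genes, 11 rose and none fell (median 0.29, camera adjusted p = 0.00297, and adjusted p = 0.133 with an estimated correlation), SCP2 (0.85) and ABCD3 (0.52) among them. Of 11 PPAR targets, 7 rose and 2 fell, and the list was not called (camera adjusted p = 0.591). Its median was 0.27 and its mean -0.49, and the falls were CPT1A and PDK4, the kinase that inhibits pyruvate dehydrogenase, which went from 1.09 to 0.0179 CPM.

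Energy metabolism and translation genes were higher by small amounts in SUM159. Of 34 nuclear-encoded complex I genes, 21 rose and none fell (median 0.19, camera adjusted p = 0.0128, and adjusted p = 0.505 with an estimated correlation), NDUFB5 (0.88) and NDUFV3 (0.53) among them. Of 39 genes of complexes II to V, 25 rose and 3 fell (median 0.23, camera adjusted p = 0.00128, and adjusted p = 0.50 with an estimated correlation), with ATP5PF (0.75) and ATP5PB (0.63) as examples. Of 24 TCA cycle genes, 13 rose and 2 fell (median 0.26, camera adjusted p = 0.0170, and adjusted p = 0.204 with an estimated correlation), SUCLG1 (0.68) and MDH1 (0.59) among them. Of 24 glycolysis genes, 15 rose and 8 fell (median 0.23, camera adjusted p = 0.0372, and adjusted p = 0.353 with an estimated correlation). PKM (0.48) and LDHA (0.45) rose, and the call was lost without scramble replicate 4 (camera adjusted p = 0.0605) or without shCPT1 replicate 1 (0.0598), within a range of 0.00535 to 0.0684. Of 62 mitochondrial ribosomal protein genes, 48 rose and 6 fell (median 0.31, camera adjusted p = 4.7e-06, and adjusted p = 0.450 with an estimated correlation), MRPS6 (0.93) among them. ATP5PF and MRPS6 lie in a stretch of chromosome 21, from 17.5 to 37.3 Mb, with a median log2 fold change of 0.46. NDUFV3 lies in the rest of that chromosome, with a median of 0.23. The rises of these examples cannot be set apart from that of the chromosome. Of 74 cytosolic ribosomal protein genes, 49 rose and 2 fell (median 0.23, camera adjusted p = 7.83e-05, and adjusted p = 0.50 with an estimated correlation), RPS3 (0.50) among them. The ATF4 and integrated stress response list had 18 of 35 genes higher and 10 lower (median 0.25, camera adjusted p = 0.00366, and adjusted p = 0.235 with an estimated correlation), the serine synthesis gene PHGDH (1.16), the amino acid carrier SLC7A5 (1.01) and CTH (1.52) among the rises. Of 15 luminal markers, 8 rose and 2 fell (median 0.37, camera adjusted p = 0.0175, and adjusted p = 0.265 with an estimated correlation), CLDN4 (1.99) and KRT8 (0.58) among them.

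Replicate 3 of shCPT1 stood apart from replicates 1 and 2, with a chi-square per degree of freedom of 8.40 and 8.27 to them, against 2.16 between the other pair. In replicates 1 to 3 the mean log2 level was 5.08, 5.11 and 5.26 for complex I genes, against 4.97 to 5.03 in scramble, and 5.83, 5.86 and 6.03 for mitochondrial ribosomal genes, against 5.65 to 5.67. Without replicate 3 the medians were 0.15 for complex I (camera adjusted p = 0.0366), 0.18 for complexes II to V (0.00348), 0.24 for mitochondrial and 0.19 for cytosolic ribosomal genes (2.31e-05 in each), so these calls held at the preset correlation, while with an estimated correlation none of the 4 was called even with replicate 3 (lowest adjusted p = 0.450).

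Log2 fold changes in SUM159 fell with transcript length across genes, which are not independent replicates (Spearman's rho -0.286, against -0.0326 in SUM149). The median length of the longest annotated transcript was 2781.5 bases for genes called higher and 4560 for genes called lower. With a length trend removed in a rank-based camera test, chosen after seeing the data, the calls of complex I (adjusted p = 0.116), complexes II to V (0.0567), the TCA cycle (0.0567), glycolysis (0.102) and DNA methylation (0.116) were lost. The median fell from 0.26 to 0.11 for the TCA cycle and moved from -0.35 to -0.10 for DNA methylation, while glycolysis kept more of its own (0.23 to 0.17). The medians of lists still called moved as well, to 0.13 for cytosolic and 0.21 for mitochondrial ribosomal genes, -0.13 for Src and focal adhesion genes (adjusted p = 0.0452) and -0.28 for YAP and TEAD targets (0.00714). None of these 4 lists was called with an estimated correlation (lowest adjusted p = 0.352). Those of the ATF4 (0.0532) and luminal (0.0694) lists were lost by the rank-based test alone, and the DNA replication list was called lower with the trend removed (0.0369).

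Besides PPAR targets, 14 lists tested in SUM159 were not called. Estrogen response genes had 18 of 30 lower and 6 higher (camera adjusted p = 0.061, called at 0.0443 without scramble replicate 1 and 0.0407 without shCPT1 replicate 1, in a range of 0.0134 to 0.116), with IGFBP5, a binding protein of insulin-like growth factors, down by 2.28 and IGFBP4 up by 0.63 on the log2 scale. Histone genes had 8 of 19 higher and 1 lower (0.0925; H2AC6 1.23). Basal markers had 4 of 20 higher and 11 lower (0.170), KRT81 (2.21) against TP63 (-1.49) and KRT17 (-1.26). Of 32 DNA replication genes 7 were higher and 16 lower (0.170, called at 0.0426 without a low-count filter, in a range of 0.0426 to 0.251), with E2F2 (-0.92) and TK1 (0.43) on opposite sides. The unfolded protein response had 11 of 20 higher and 5 lower (0.170; XBP1 0.42, ERN1 -0.86). Hypoxia targets had 9 of 23 higher and 8 lower (0.200; EGLN3 1.19, MXI1 -0.97). Lipid droplet genes had 4 of 14 higher and 6 lower (0.206), among them MGLL, a monoacylglycerol lipase (-1.52). The p53 targets had 5 of 22 higher and 11 lower (0.394; CDKN1A -0.76, CCNG1 0.52). Fatty acid uptake genes had 4 of 14 each way (0.462; LPL 1.34). Lysosome genes had 7 of 25 higher and 10 lower (0.462; CTSB -0.88, LAMP2 0.50). Fatty acid synthesis genes had 5 of 20 higher and 6 lower (0.609; ME1 0.81, SCD5 -0.57). Interferon-stimulated genes had 14 of 26 higher and 7 lower (0.641; IFI44L 1.32, HERC5 -1.86). Heat shock and immediate early genes had 7 of 19 each way (0.724; HSPA8 0.62, JUNB -1.19). MHC class I genes had 3 of 10 higher and 4 lower (0.741; PSME2 0.39, ERAP2 -0.28). Median, mean and test differed in sign in 5 lists, PPAR targets among them, and none of the 5 was called. Adjusted over the list alone, the counts changed in 3 lists: 1 NF-kappaB gene was higher, 50 and 3 cytosolic ribosomal genes were higher and lower, and 8 and 11 lysosome genes.

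The second comparison asks what etomoxir does to SUM149 cells. With the drug, PPAR targets and genes of the ATF4 stress response rose, and genes of lipid synthesis and of the cell cycle and mesenchymal markers mostly fell. ANGPTL4, a lipase inhibitor and PPAR target (ENSG00000167772, chromosome 19, 8363289 to 8374373), rose 38-fold, from 31.0 ± 1.38 to 1184 ± 30.2 CPM (SD, n = 3 and 3). PLIN2, which coats lipid droplets, rose 20.8-fold to 581.7 ± 17.4 CPM, and TRIB3, a pseudokinase induced by ATF4, rose 3.37-fold to 316.3 ± 2.87 CPM. SCD, the stearoyl-CoA desaturase, fell 2.88-fold, from 2059 ± 29.8 to 719.0 ± 10.5 CPM. Of 15150 genes tested, 4920 were higher and 4835 lower with etomoxir (edgeR, adjusted p under 0.05), 791 and 1029 of them by at least 2-fold.

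Among the 10 largest rises in SUM149, the cytokine IL24 (ENSG00000162892, chromosome 1, 206897443 to 206904139) rose 41.0-fold to 73.1 ± 2.66 CPM (log2 fold change 5.36, SE 0.101, edgeR adjusted p = 3.25e-51), PDK4 rose 23.1-fold to 195.4 ± 11.6 CPM, and SHH, the hedgehog ligand, rose 23.8-fold to 80.6 ± 1.59 CPM. Others were ANGPTL4 (5.25), NOS3 (5.14), FGF21 (4.76), ACSBG1 (4.66), SH2D5 (4.38) and PLIN2 (4.38). STC1, the hormone stanniocalcin 1 (ENSG00000159167, chromosome 8, 23841915 to 23854807), fell 15.7-fold, from 934.1 ± 12.3 to 59.95 ± 1.66 CPM (log2 fold change -3.97, SE 0.034, edgeR adjusted p = 7.41e-71). The other large falls were SBSPON (-5.30), SNCAIP (-5.00), IL22RA2 (-4.61), ASTL (-4.27), FOXI1 (-4.13), B3GAT1 (-4.09), CEMIP (-3.77), TNFAIP6 (-3.63) and IL7R (-3.63). SRC was at 74.9 ± 3.57 CPM in water and 71.8 ± 3.69 CPM with etomoxir (log2 fold change -0.07, SE 0.047, edgeR adjusted p = 0.215). ESR1 had 31 to 50 reads per water library and 13 to 27 per etomoxir library (log2 fold change -0.72, SE 0.282, edgeR adjusted p = 0.0218). The ESR1 call was lost in DESeq2 (adjusted p = 0.0681), without water replicate 1 (edgeR adjusted p = 0.148) and without etomoxir replicate 3 (0.186), in a range of 0.0095 to 0.186 over the alternatives. PGR had 1 read in 1 water library.

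Of 34 lists tested in SUM149, camera called 7 higher and 11 lower, and 7 of the 18 held with an estimated correlation. Of 35 ATF4 and integrated stress response genes, 33 rose and 2 fell (median 1.19, camera adjusted p = 2.66e-48, and adjusted p = 0.0128 with an estimated correlation). STC2 (2.66), PPP1R15A (2.36), TRIB3 (1.75) and the serine synthesis gene PSAT1 (1.48) were among them. Of 15 PPAR targets, 13 rose and 2 fell (median 0.59, camera adjusted p = 6.87e-35, and adjusted p = 0.00604 with an estimated correlation). All 30 tested G2 and M phase genes fell (median -0.71, camera adjusted p = 3.75e-18, and adjusted p = 0.035 with an estimated correlation), KIF20A (-1.31) and CCNB1 (-0.88) among them. Of 32 DNA replication genes, 30 fell and none rose (median -0.60, camera adjusted p = 4.52e-10, and adjusted p = 0.0193 with an estimated correlation), RRM1 (-0.91) and TK1 (-0.88) among them. Of 25 genes of cholesterol synthesis and uptake, 21 fell and 1 rose (median -0.66, camera adjusted p = 2.89e-12, and adjusted p = 0.0193 with an estimated correlation), with DHCR7 (-0.66) as an example. Of 18 genes of fatty acid synthesis and desaturation, 14 fell and 4 rose (median -0.31, camera adjusted p = 9.36e-07, and adjusted p = 0.0282 with an estimated correlation), among them FADS2 (-1.76), SCD (-1.53), SREBF1 (-1.38), the transcription factor of lipid synthesis, and FASN (-0.97). Of 27 mesenchymal markers, 18 fell and 4 rose (median -0.86, camera adjusted p = 4.64e-14, and adjusted p = 0.0257 with an estimated correlation). FN1 went from 2203 ± 55.7 to 465.8 ± 17.4 CPM, and LOX (-2.80) and THBS1 (-1.33) fell with it.

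The other 11 calls in SUM149 were lost with an estimated correlation. Of 18 lipid droplet genes, 10 rose and 4 fell (median 0.23, camera adjusted p = 9.36e-07, but adjusted p = 0.056 with an estimated correlation), G0S2, an inhibitor of lipolysis (2.94), among them. Of 14 fatty acid uptake genes, 6 rose and 5 fell (median 0.22, camera adjusted p = 0.00826, and adjusted p = 0.147 with an estimated correlation). FABP4 (2.79), FABP3 (2.12) and ACSL1 (1.47) were among the rises. Respiratory and TCA cycle genes were mostly lower. In complex I, 25 of 34 genes fell and 1 rose (median -0.19, camera adjusted p = 0.025, and adjusted p = 0.329 with an estimated correlation), NDUFB4 (-0.57) among them. In complexes II to V, 30 of 39 fell and 1 rose, the cytochrome c gene CYCS (0.50), with a median of -0.20 (camera adjusted p = 0.00826, and adjusted p = 0.382 with an estimated correlation). In the TCA cycle, 17 of 24 fell and 3 rose (median -0.24, camera adjusted p = 0.000697, and adjusted p = 0.0853 with an estimated correlation), PC, pyruvate carboxylase (-1.54), and IDH2 (-1.29) among the falls. In glycolysis, 14 of 24 fell and 4 rose (median -0.23, camera adjusted p = 0.0222, and adjusted p = 0.171 with an estimated correlation), PKM (-0.73) against the lactate carrier SLC16A1 (0.48). That glycolysis call was lost at a mean of at least 5 CPM (camera adjusted p = 0.0514), the highest over those settings, from 0.00134. Of 18 histone genes, 15 fell and none rose (median -1.02, camera adjusted p = 0.000585, and adjusted p = 0.0578 with an estimated correlation), H2BC11 (-1.85) and H1-2 (-1.18) among them. Of 73 cytosolic ribosomal protein genes, 64 rose and 1 fell (median 0.24, camera adjusted p = 1.14e-07, and adjusted p = 0.329 with an estimated correlation), RPL35A (0.48) among them.

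In the last 3 called lists of SUM149, members went both ways. NF-kappaB genes had 13 of 25 lower and 11 higher (median -0.15, camera adjusted p = 0.00455, and adjusted p = 0.0836 with an estimated correlation), with CXCL1 (-2.84) and PTGS2 (-2.16) against IL1A (2.12). The p53 targets had 10 of 23 higher and 7 lower (median 0.05, camera adjusted p = 0.0208, and adjusted p = 0.125 with an estimated correlation), CDKN1A (1.31) and GDF15 (2.64) among the rises. Heat shock and immediate early genes had 8 of 20 higher and 9 lower and were called higher (camera adjusted p = 0.0208, and adjusted p = 0.125 with an estimated correlation). Their median was -0.03 and their mean 0.11, with FOSL1 (2.18) and JUN (2.17) above HSP90AA1 (-0.51). A rank-based camera test, chosen after seeing the data, ended the calls of lipid droplets (adjusted p = 0.124), fatty acid uptake (0.404), NF-kappaB (0.496), p53 targets (0.404) and heat shock (0.956). A fit over all 13 libraries ended those of NF-kappaB (0.0548, in a range from 5.13e-05) and heat shock (0.150, in a range of 0.00284 to 0.209).

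Among the 16 lists not called in SUM149, interferon-stimulated genes had 15 of 24 lower and 1 higher (camera adjusted p = 0.0612; IFI6 -1.23), and passed at 0.013 in the fit over all 13 libraries, in a range of 0.013 to 0.183 over those settings, and at 0.00212 by the rank-based test. The unfolded protein response had 11 of 20 lower and 8 higher (0.0621, and 0.0432 without water replicate 1, in a range of 0.0103 to 0.132), PDIA4 (-1.14) against ERN1 (1.87). NRF2 targets had 10 of 25 higher and 9 lower (0.188, and 0.0425 without a low-count filter, in a range of 0.0425 to 0.347), HMOX1 (3.05) and SLC7A11 (1.52) against EPHX1 (-0.81), while NQO1 had a log2 fold change of -0.02. Mitochondrial beta-oxidation genes had 10 of 23 higher and 7 lower (0.227), ACADVL (0.91) and HADHB (0.75) against PPARGC1A (-1.89). Src and focal adhesion genes had 9 of 26 higher and 14 lower (0.279; EGFR 0.72, CAV1 -1.11). MHC class I genes had 4 of 8 higher and 1 lower (0.562; NLRC5 1.13), estrogen response genes 11 of 33 higher and 15 lower (0.562; MYC 1.20, IGFBP5 -2.80), and mitochondrial ribosomal genes 25 of 62 higher and 16 lower (0.562; MRPS23 0.51). Lysosome genes had 6 of 25 higher and 15 lower (0.569; SQSTM1 1.05, CTSD -1.02), and peroxisomal genes 4 of 17 higher and 7 lower (0.569; SCP2 -0.70). Luminal markers had 10 of 24 higher and 11 lower (0.571; CLDN4 0.66, KRT19 -1.21), and basal markers 10 of 25 higher and 14 lower (0.668; KRT17 -1.19). LAMB3, a basal marker and chain of laminin 332, rose 3.05-fold, from 2614 ± 27.0 to 8030 ± 204 CPM. Leucocyte and endothelial markers had 2 of 5 higher and 3 lower (0.571; CSF1R 1.59, PECAM1 -1.65). YAP and TEAD targets had 11 of 23 higher and 10 lower (0.729; AXL 2.13, TGFB2 -2.68). Hypoxia targets had 9 of 23 higher and 8 lower (0.895; VEGFA 1.21, LOX -2.80), and DNA methylation genes 5 of 19 higher and 7 lower (0.982; DNMT1 -0.62). Median, mean and test differed in sign in 6 lists, of which heat shock was called. Adjusted over the list alone, 65 cytosolic ribosomal genes were higher, 5 lipid droplet and 17 mitochondrial ribosomal genes were lower, and 12 and 11 YAP and TEAD targets were higher and lower.

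**Figure D2:**
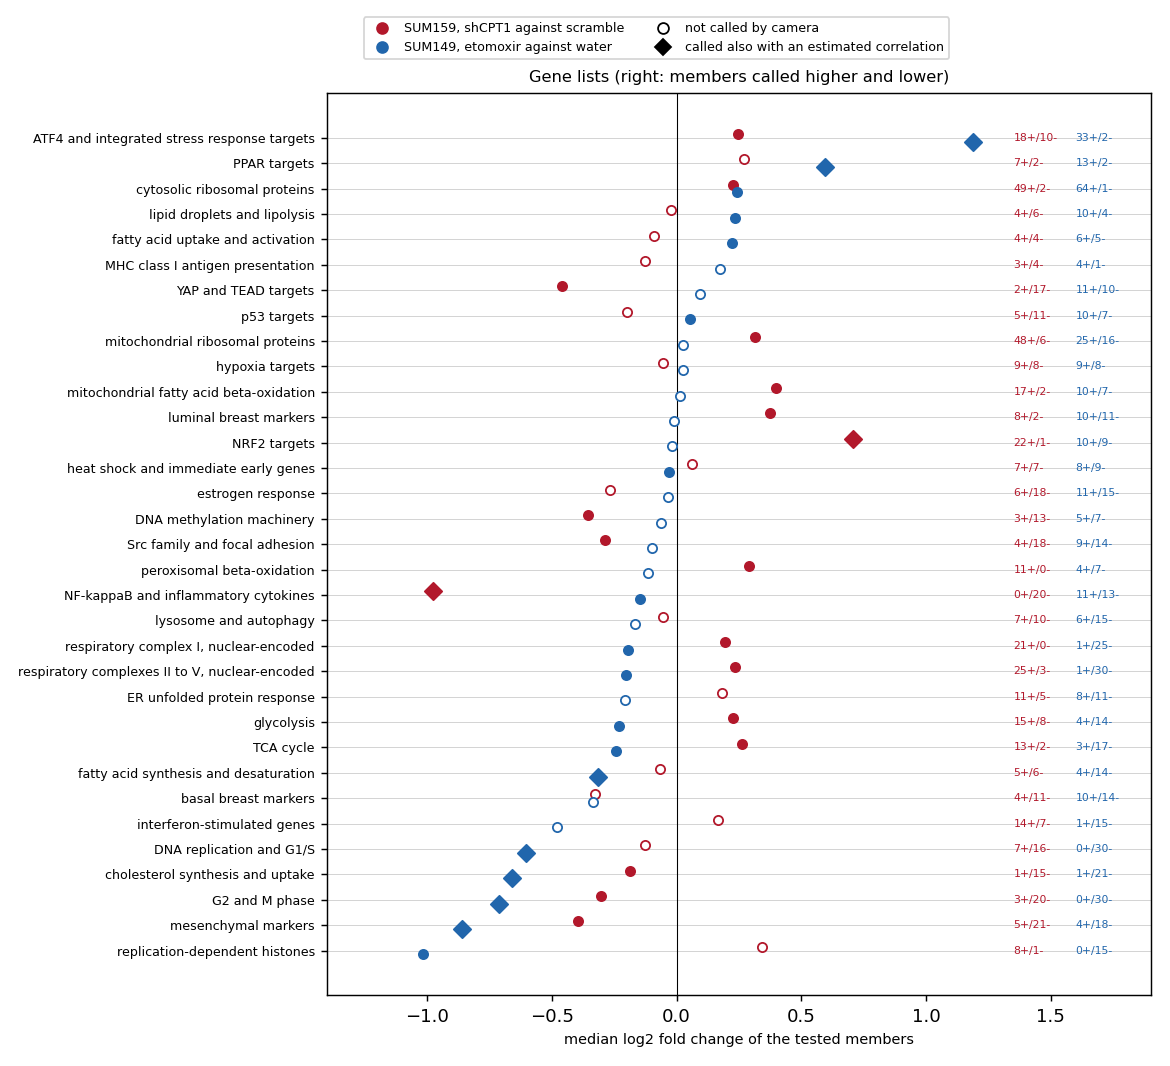
Median log2 fold change of each gene list with shCPT1 in SUM159 and with etomoxir in SUM149, filled where camera called the list and as a diamond where the call held with an estimated correlation, with the numbers of members called higher and lower at the right. The ATF4 list stood at 0.25 and 1.19, and the NRF2 list at 0.71 and -0.02.

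The third comparison asks whether the hairpin and the drug moved the same genes. Across 13267 genes tested in both comparisons, 1374 were higher in both and 1589 lower in both, while 1495 rose with shCPT1 and fell with etomoxir and 1482 did the opposite. Independent lists of these sizes would share 1388 higher genes (exact hypergeometric p = 0.718), 1405 lower genes (2.37e-13), 1368 (2.68e-07) and 1425 (0.0133), and these p-values treat genes as independent, which they are not. The log2 fold changes had a Pearson correlation of 0.018 and a Spearman correlation of 0.001 across genes. Genes raised in both included ABCG2, a drug efflux pump (2.05 in SUM159 and 1.48 in SUM149), ADGRB2 (1.33 and 1.33), TRNP1 (0.99 and 1.11), CHAC1, which degrades glutathione (1.25 and 2.13), and HMOX1, heme oxygenase 1 (1.05 and 3.05). Genes lowered in both included FN1 (-2.89 and -2.25), IGFBP7 (-2.83 and -1.92), DMBT1 (-2.57 and -3.23), CEMIP, a hyaluronan-degrading protein (-2.54 and -3.77), ARNT2 (-2.50 and -2.31) and IGFBP5 (-2.28 and -2.80). STEAP4, a metalloreductase (2.20 and -2.55), LAPTM5 (2.17 and -2.45) and SAMD11 (2.14 and -1.60) rose with shCPT1 and fell with etomoxir, and GDF15, a stress-induced cytokine (-1.54 and 2.64), did the opposite.

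The test of the difference itself, etomoxir effect minus shCPT1 effect, was above 0 for 4391 genes and below 0 for 4628 of 17126 (edgeR, adjusted p under 0.05). Only 13267 genes had enough reads to be tested in both lines, so for the others at least 1 of the effects rests on few reads. STEAP4 had a difference of -4.77 (SE 0.103, edgeR adjusted p = 2.16e-33) and GDF15 a difference of 4.15 (SE 0.176, adjusted p = 3.52e-23). Camera called 4 lists higher and 14 lower in this difference, 9 of them also with an estimated correlation. The etomoxir effect exceeded the shCPT1 effect by a median of 0.88 over ATF4 targets (camera adjusted p = 4.82e-14, and adjusted p = 0.00295 with an estimated correlation), and by 0.87 over NF-kappaB genes, which fell further with shCPT1 (0.00146, and adjusted p = 0.0221 with an estimated correlation). NRF2 targets had a median difference of -0.63 (camera adjusted p = 1.47e-07, and adjusted p = 0.0186 with an estimated correlation), and TCA cycle genes -0.48 (3.68e-07, and adjusted p = 0.00295 with an estimated correlation). DNA replication genes (-0.39), histones (-1.52), cholesterol genes (-0.37), peroxisomal genes (-0.42) and the unfolded protein response (-0.39) also had differences below 0, with adjusted p of 0.00295, 0.0221, 0.0166, 0.0353 and 0.0456 with an estimated correlation. Complex I genes had a median difference of -0.43 (camera adjusted p = 2.23e-05, but adjusted p = 0.249 with an estimated correlation), and those of complexes II to V -0.46 (3.68e-07, but adjusted p = 0.260 with an estimated correlation). Glycolysis (-0.29), fatty acid synthesis (-0.29) and G2 and M phase genes (-0.47) were called by camera at 0.000295, 0.0011 and 2.23e-05, each with adjusted p = 0.0657 with an estimated correlation. Interferon-stimulated genes (-0.54, camera adjusted p = 0.0104) and mitochondrial ribosomal genes (-0.28, 0.00166) had differences below 0, with adjusted p of 0.140 and 0.477 with an estimated correlation. YAP and TEAD targets (0.49, camera adjusted p = 0.0011) and p53 targets (0.20, 0.0271) had differences above 0, with adjusted p of 0.249 and 0.0657 with an estimated correlation. PPAR targets had a median difference of 0.52 that was not called (camera adjusted p = 0.0913), and cytosolic ribosomal genes one of -0.02 (0.839). Cell line and kind of inhibition differ together, so the difference cannot be assigned to either. No length trend was removed from these differences.

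**Figure D3:**
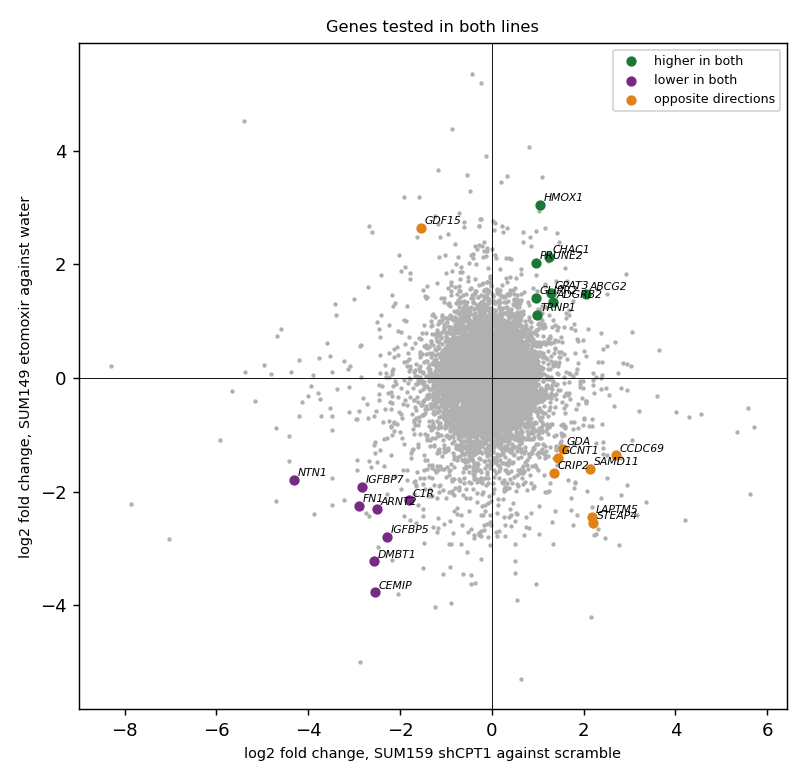
Log2 fold change with etomoxir in SUM149 against log2 fold change with shCPT1 in SUM159, 1 point for each of the 13267 genes tested in both, with the genes named for this comparison labelled. The Pearson correlation across genes was 0.018.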

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

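The tests for vector transcripts, for mixed cells, for the place of OTUD6A, MIR30A and ALPP, for the ribosomal and the respiratory lists apart and for PPAR targets at or under 1 CPM were chosen only after the results were seen. The splits of the libraries were planned. For the other tests, those with length and GC trends removed among them, the expected outcome was written before the value was computed but after the pattern had been seen.

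In the scramble group, 4 values stood far from the other libraries of the group: CPT1C at 1.23 CPM in replicate 4, C1QTNF6 at 1.65 CPM in replicate 1, TRNP1 at 12.5 CPM in replicate 4 and LAPTM5 at 2.71 CPM in replicate 4. Chance gives about 1 such value in 20 groups, which is 2.45 for the 49 groups tested. Between the lines, 4 lists were called higher in SUM159 and lower in SUM149 by camera at its preset correlation. With an estimated correlation none of these 8 calls held (lowest adjusted p = 0.204 in SUM159 and 0.0853 in SUM149), and with the length trend removed the 4 in SUM159 were lost as well (lowest adjusted p = 0.0567). Their median difference, etomoxir effect minus shCPT1 effect, was -0.43 for complex I, -0.46 for complexes II to V, -0.48 for the TCA cycle and -0.29 for glycolysis. With an estimated correlation the call of this difference held for the TCA cycle (adjusted p = 0.00295) and was lost for complex I (0.249), complexes II to V (0.260) and glycolysis (0.0657). The length trend was removed only within each line, so the difference was not tested without it. In SUM159 that removal took the TCA cycle median from 0.26 to 0.11. The effect differed for 9019 of 17126 genes, a set that includes genes with too few reads to be tested in 1 of the lines.

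The first pattern holds OTUD6A, MIR30A and ALPP, which rose steeply in SUM159 shCPT1, and stretches of chromosomes that moved together. Admixed SUM149 cells are argued against, since genes found in SUM149 alone stood at a median of 0.143% of their SUM149 level while ALPP stood at 119.9%. Copy number differences in a subclone are a candidate explanation for the stretches of chromosome 2, which hold 8 of the 12 windows of 50 neighbouring genes that passed all shuffled orders, but 0 of the 3 genes lies in such a stretch. The other 4 windows, on chromosomes 19 and 21, stood less apart from the rest of their chromosome or not at all once length and GC trends were removed (-0.32 against -0.22, and 0.35 against 0.36). Both parts of chromosome 21 stayed above 0, so a copy number difference of that whole chromosome stays open. MIR30A exceeded its host LINC00472 by 3.62 (SE 0.242) on the log2 scale and had reads in lentivirus libraries alone, which are all SUM159. The counts may come from the vector, though virus and line cannot be told apart by where reads occur. What raised OTUD6A and ALPP stays open, the knockdown itself included.

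The second pattern holds the ribosomal and respiratory lists, whose short genes rose in SUM159 shCPT1. GC content is argued against by the 4 of 4 lists still called with its trend removed. The lowest median of 0.169 under RLE or total-count scaling leaves scaling open, since these moved the median over all genes by only 0.004 and -0.023 and no list could have reached 0. With the length trend removed, 2 of the 4 lists were still called, so length alone cannot be told apart from the knockdown for the 4 together, since a part of them held. Both ribosomal lists (2 of 2) kept their call with medians down from 0.23 and 0.31 to 0.13 and 0.21, though neither was called with an estimated correlation (adjusted p = 0.50 and 0.450), and complexes I and II to V (0 of 2) lost theirs with medians down from 0.19 and 0.23 to 0.06 and 0.09, so a length bias may account for the latter, and an effect of the knockdown stays open.

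The third pattern is the list of PPAR targets, called higher with etomoxir in SUM149 and not called with shCPT1 in SUM159, while the difference itself was not called (camera adjusted p = 0.0913). Silence of these genes in SUM159 is argued against for 8 of the 13 targets called higher in SUM149, which were above 1 CPM in scramble. Their median log2 fold change was 0.17 there against 0.54 in SUM149, or 0.22 against 0.51 without CPT1A, which the hairpin lowered (-2.86), though SLC25A20 (0.68 against 0.59) and CAT (0.58 against 0.22) rose more in SUM159 and ACOT2 rose about as much (0.27 against 0.28). PDK4 was only just above the cut, at 1.09 CPM in scramble. All 8 were picked as called higher in SUM149, which favours a higher median there. For the other targets called there, such as ANGPTL4 and PLIN2, at or under 1 CPM in scramble, 0 passed 1 CPM with shCPT1, so silence cannot be told apart from a lack of induction. The median difference over all PPAR targets was 0.52, and line and agent cannot be told apart because the design changes them together.

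Among splits of the same libraries, the real split alone called genes in SUM159 (9361, against 0 in the highest other of 35 splits, 1 as large). The other splits put shCPT1 and scramble libraries in the same group, which raises the spread, so their 0 says little. Replicates may be technical, so a chance difference between single cultures cannot be excluded. For the number of lists called there (18, and 18 in another split, 2 of 35 in all) the splits cannot decide. That other split set scramble replicates 1, 2 and 4 against replicate 3 and all shCPT1 libraries, so it carried most of the real contrast. In SUM149 the 10 splits are too few to exclude chance (9755 genes against 0, 18 lists against 11, 1 split as large in each). For the 2963 genes shared in direction, 2 of 700 pairs of splits did as well, the other being the real split mirrored in 1 line with 2977. All other splits of each line called 0 genes and had none to share, so this number tells nothing about sharing. The 9019 genes whose effect differs were more than in any other split drawn (3066 in the highest other of 60, 1 as large). This bears on the grouping of these libraries and cannot exclude a chance difference between cultures.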

How the results depend on the processing

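Counts of genes per direction stayed within 1.5 times their reported values under every alternative run: in SUM159 3822 to 4837 higher and 3751 to 5009 lower, in SUM149 4044 to 5030 and 4016 to 4929, and for the difference 3709 to 4806 and 3938 to 4781. Shared genes ranged from 1186 to 1384 higher in both, 1315 to 1698 lower in both and 2576 to 3003 in opposite directions. With each library left out, SUM159 gave 4298 to 4479 higher and 4456 to 4673 lower, and SUM149 4639 to 4771 and 4567 to 4741. Counts of at least 2-fold changes moved with the filter, because fewer or more genes were tested: at a mean of at least 5 CPM they were 167 and 343 in SUM159 and 341 and 502 in SUM149, and without a filter 943 genes were higher in SUM159. Numbers of lists moved with the test. With an estimated correlation 1 was higher and 1 lower in SUM159, and 2 and 5 in SUM149. With fry 14 were lower in SUM159, and 12 higher and 19 lower in SUM149. With the length trend removed, chosen after seeing the data, 5 were higher in SUM159. The rank-based test, likewise chosen later, gave 3 higher in SUM149 with or without that trend. It also turned the heat shock list to lower, at medians of -0.031 and, with the trend removed, -0.032, not called. CPT1B in SUM149 turned to -0.12 without water replicate 1 and to -0.13 without etomoxir replicate 3, a range of -0.13 to 0.29 over the libraries left out, at few reads. The cause of these changes was not tested. Replicate numbers paired the libraries weakly at most: deviations of same-numbered libraries correlated at 0.004 to 0.055 in SUM159 and 0.003 to 0.029 in SUM149, and 3 of 6 and 5 of 6 libraries correlated best with their own number. A weak pairing in SUM149 is thus not excluded. With the number as a replicate block, 4293 genes were higher and 4572 lower in SUM159, 4956 and 4873 in SUM149, the glycolysis list in SUM159 (adjusted p = 0.0684) and the heat shock list in SUM149 (0.209) were not called, and the interferon list in SUM149 was (0.0311). Depth limits genes such as CPT1B, CPT1C, ESR1 and PGR, with few reads per library.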

Other observations

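Long noncoding RNA genes and pseudogenes leaned upward in both lines. In SUM159, 356 of 1422 long noncoding RNA genes tested were higher with shCPT1 and 255 lower, and 309 of 1074 pseudogenes were higher and 134 lower, while 3918 of 12375 protein-coding genes were higher and 4366 lower and 7 of 78 genes of other kinds higher and 16 lower. In SUM149, 506 of 1617 long noncoding RNA genes were higher with etomoxir and 236 lower, and 256 of 987 pseudogenes were higher and 136 lower, while 4145 of 12454 protein-coding genes were higher and 4449 lower and 13 of 92 of other kinds higher and 14 lower. Processed pseudogenes took 2.97% of counts in scramble and 3.58% in shCPT1, and 2.68% in water and 3.01% in etomoxir, as group means. In shCPT1 replicates 1 to 3 the shares were 3.44%, 3.45% and 3.84%, highest in the replicate that stood apart. Whether transcript length has a part in the lean in SUM159 was not tested. PPARG, the adipogenic member of its receptor family, stood at 13.6 CPM in SUM159 scramble and 79.3 CPM in SUM149 water, PPARA at 13.6 and 23.6 CPM, and PPARD at 51.7 and 54.9 CPM.

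Around OTUD6A on chromosome X, EDA, a ligand of the tumour necrosis factor family, fell from 10.3 to 1.21 CPM in SUM159 (log2 fold change -3.09). AWAT2 rose by 1.66 on the log2 scale, from 0.689 to 2.17 CPM, and KIF4A, a mitotic kinesin, fell by 0.61. The other neighbours tested moved little, from -0.19 (DLG3) to 0.41 (PDZD11), and RAB41, DLG3, TEX11 and SNX12 were not called. Around ALPP the neighbours went both ways. ALPG, a close paralog, rose by 4.01, EFHD1 by 1.34 and NGEF, 500 kb away, by 2.94, while SNORC fell by 1.55, DGKD by 0.64 and GIGYF2 by 0.45 and TIGD1 was not called (log2 fold change 0.19, edgeR adjusted p = 0.226). In SUM159, 74 of 90 genes on chromosome 2 between 88.7 and 113.5 Mb were below 0, with a median log2 fold change of -0.46, and 56 of 70 between 118.0 and 149.2 Mb, with a median of -0.39. After trends on length and GC content were removed these medians were -0.47 and -0.40, against 0.00 and -0.01 for the rest of the chromosome. On chromosome 21, 46 of 60 genes between 17.5 and 37.3 Mb were above 0, with a median of 0.46, and the rest of that chromosome had a median of 0.23. After both trends were removed the stretch stood at 0.35 and the rest at 0.36, so the chromosome as a whole stayed raised. On chromosome 19, 60 genes between 53.4 and 57.4 Mb, 27 of them zinc finger genes, had a median of -0.47, against -0.30 for the rest, and -0.32 against -0.22 after both trends were removed. In SUM149, 50 genes on chromosome 6 between 25.1 and 28.2 Mb, 22 of them histone genes and 9 zinc finger genes, had a median of -0.49 with etomoxir, and of -0.25 without these.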
